A study of Mus musculus with 19 samples.

How the data were processed

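RNA was sequenced from the caecum of female C57BL/6 mice, as 19 samples in 4 groups with 1 library per sample: 5 control samples, 4 samples labelled as infected with the whipworm Trichuris muris (T. muris), and 5 samples at each of 2 doses of a garlic extract given to infected mice. Per the labels the extract was 40% PSTO and the doses were 0.1 and 1 mg per kg body weight. The study's description puts the tissue collection at day 35 of the infection. The labels give no sequencing batch, and they do not state that each replicate number is a separate animal, so the p-values measure the spread between samples. Per the labels total RNA was extracted with a Qiagen kit and sequenced by a standard Illumina protocol. A label on cell culture and lipopolysaccharide is attached to every sample. It does not describe caecum tissue and was not used.

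The deposited table holds raw read counts per gene for each sample, whole numbers that the authors had not normalised. The authors' notes name HISAT, DESeq2 and the genome build mm39. They give no versions and no role for either tool, and the program that counted the reads, the annotation release and the strand setting are not given in the sources used here. The table lists 55137 loci, of which 20218 had 0 counts in every sample. A total of 1336 loci carry no gene name and took 0.299% to 0.468% of each sample's counts. They were left out of the library sizes and the tests, and were kept in an alternative. Of the 53801 loci with an Ensembl gene ID, 53620 IDs matched the GENCODE vM21 annotation. That annotation is of another genome build than the one the authors name, so it was used for gene names only and no coordinates are given. A spreadsheet program had turned 14 gene symbols into dates, and all 14 were restored through their IDs. Another 254 loci share a symbol with a different ID and were kept apart by ID.

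Totals per sample ran from 16402029 to 30779218 counts. At these depths 3 counts, the number that a count of 0 allows, correspond to between 0.0979 and 0.184 CPM (counts scaled to library size). Intervals on counts cover counting error only. To look for duplicated or split libraries, replicates were compared for a spread no larger than counting noise. The smallest chi-squared per degree of freedom between replicates was 11.6, so no pair of libraries differed by counting noise alone.

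Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. All 19 samples went into 1 quasi-likelihood fit with robust estimation, with 15 residual degrees of freedom. Scaling was by trimmed mean of M values (TMM). The filterByExpr function with the groups, a minimum count of 10 and a minimum total of 15 left 19050 genes. The common biological coefficient of variation was 0.249. There were 6 comparisons, each a contrast of this fit: infected against control, each dose against infected, the higher dose against the lower, and each dose against control. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no minimum fold. CPM values use TMM-scaled library sizes. Standard errors (SE) of log2 fold changes come from the quasi-likelihood F statistic, and 95% intervals from that SE. On data simulated with the fitted dispersions and the same samples, 4-fold changes were found for 75.8% to 90.9% of 66 genes across the 6 comparisons, 2-fold changes for 53.7% to 73.1% of 67 genes, and 1.5-fold changes for 23.9% to 44.8% of 67 genes. Between 3 and 5 unchanged genes were called in each simulated comparison. Each comparison had 1 simulated data set, in which only these few genes changed and each gene was drawn independently. The share found depends on how many genes change, so these shares are not the power of the real comparisons.

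Before the data were examined, 41 gene lists were fixed, with markers of epithelial, immune, muscle, nerve, vascular and fat cells, of neighbouring tissue, and of signalling and metabolic pathways. Each list was tested with camera at a preset correlation between genes of 0.01, with adjustment over the 41 lists of a comparison. Beside it stand camera with a correlation estimated for each list and fry, which tests whether the genes of a list move on balance one way and does not compare the list with other genes. Counts of members that passed are given adjusted over all genes and adjusted over the list alone. A list score is the mean over members of log2 CPM (prior count 2) minus each gene's mean over all 19 libraries. Similar scores were made afterwards for mesothelial genes and for genes of lymphoid follicles.

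The genes to name were set by a rule before the data were examined. For infected against control and for each dose against infected it took the 6 largest rises and the 6 largest falls among genes that passed, with a mean log2 CPM of at least 1 and CPM ranges of the 2 groups that do not overlap. For the other 3 comparisons it took 3 in each direction. It passed over predicted gene models, pseudogenes and immunoglobulin or T cell receptor segments. It added 3 members with the smallest adjusted p from each of up to 6 lists with the smallest camera p, 12 readouts of the host response to Trichuris whatever their values, and the 5 genes with the smallest unadjusted p where fewer than 5 passed. Any other gene named below was chosen after its values were seen.

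The covariance of fold changes across genes was computed for infection and each dose, and for the 2 doses. Because these comparisons share the infected libraries, it was set beside 100 simulations of unchanged groups and beside all 6 divisions of the infected libraries into 2 and 2 with no library shared. The overlap of genes called against control was set beside the number that independent lists would share and beside 20 divisions of the controls. Alternatives fixed beforehand were RLE and upper-quartile scaling, no count filter, a filter at a mean CPM of 5, DESeq2 1.42.0, limma voom with sample weights, a fit of the 2 groups alone, the replicate number as a block, each library left out, a minimum absolute log2 fold change of 1, and immunoglobulin genes left out. Added after the data were seen were loci without a gene name kept, the B cell list score as a covariate, and the libraries control 5 and T_muris 2 both left out. For each comparison, 100 of the 126 possible splits of its samples were tested. Histology, worm counts and the cell experiment that a label mentions were not analysed here. The values of 1 gene that the rule for named genes selected are not reported here.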

Results

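Gene expression was measured by RNA sequencing in caecum tissue of female C57BL/6 mice. The caecum is the site where the whipworm Trichuris muris lives. There were 5 control samples, 4 samples from infected mice, and 5 samples at each of 2 doses of a garlic extract given to infected mice, 0.1 and 1 mg per kg body weight. These groups are called control, infected, lower dose and higher dose below. Total counts per sample ran from 17030267 to 23635285 in controls, from 16402029 to 23659098 in infected samples, from 20374931 to 24250280 at the lower dose and from 20248311 to 30779218 at the higher dose. In a principal component analysis of the 2000 most variable genes, the first component held 54.2% of the variance and the next 15.1%.

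The comparison of infected with control samples asked how the caecum differed after 35 days of infection. Genes that respond to interferon gamma were among those with the largest rises. Ido1 (ENSMUSG00000031551), an enzyme that breaks down tryptophan, rose from 4.20 ± 0.809 to 582 ± 710 CPM (SD, n = 5 and 4). Cxcl9 (ENSMUSG00000029417), a chemokine that draws T cells, rose 115-fold to 525 ± 360 CPM, and the interferon gamma gene itself, Ifng (ENSMUSG00000055170), rose 113-fold to 6.23 ± 2.64 CPM. Largest among the falls were Slc30a10 (ENSMUSG00000026614), a manganese exporter, from 141 ± 28.6 to 0.702 ± 0.989 CPM, and the cytochrome P450 gene Cyp4b1 (ENSMUSG00000028713), from 103 ± 40.7 to 0.720 ± 0.198 CPM. The CPM ranges of the 2 groups did not overlap for these 5 genes. T_muris 4 held 1637 CPM of Ido1, and without it the log2 fold change was 5.77 rather than 7.11. Ifng had 5 counts in all controls together, 3 of them in control 2, so its fold is loosely set. The log2 fold change of Slc30a10 was -9.39 rather than -7.54 without T_muris 3.

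In all, 7298 of 19050 genes passed at an adjusted p under 0.05 in edgeR, 3932 higher and 3366 lower in infected samples. Of these, 1431 were higher and 1328 lower by at least 2-fold. With upper-quartile scaling, which moved the median log2 fold change of all genes from 0.016 to -0.094, 2992 were higher and 4502 lower. Without the libraries control 5 and T_muris 2, which stood apart from their groups, 5505 genes passed, 3115 higher and 2390 lower. The other genes with the largest rises were Ighg2c (ENSMUSG00000076612), an immunoglobulin G heavy chain, with a log2 fold change of 6.80 ± 0.90 (SE), the neutrophil surface gene Ly6g (ENSMUSG00000022582) with 6.79 ± 1.03, and the interferon-induced GTPase gene Gbp10 (ENSMUSG00000105096) with 6.61 ± 0.69. The other large falls were those of the calcium channel gene Trpv6 (ENSMUSG00000029868), -5.81 ± 0.80, of Cyp4f15 (ENSMUSG00000073424), -5.40 ± 0.72, of Cps1 (ENSMUSG00000025991), a urea cycle enzyme, -5.39 ± 0.72, and of Ugt8a (ENSMUSG00000032854), -4.95 ± 0.82. Adjusted p for these 12 genes lay between 1.51e-07 and 0.000137. Leaving out 1 library moved Ighg2c to 5.86 (T_muris 1), Ly6g to 7.56 (control 2), Gbp10 to 6.01 (T_muris 4), Trpv6 to -6.82 (T_muris 1) and Cps1 to -6.55 (T_muris 3).

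Of the 41 gene lists, 24 were called by camera with the preset correlation, 15 upward and 9 downward. With an estimated correlation 6 were called, the lists of interferon gamma response, cytotoxic lymphocytes, macrophages, neutrophils, unfolded protein response and mitochondrially encoded genes, and fry called 31. When the same 9 samples were split in other ways, the preset test still called a median of 21 lists. None of those splits has equal shares of infected libraries on both sides, so they can keep part of the infection difference. The number of lists also depended on the correlation used, so the counts of members that passed carry more weight. Counts of members below are over all genes tested, with the count adjusted over the list alone beside each. Of all genes 20.6% rose and 17.7% fell, so a list with shares near these does not stand out. Members of a list are also correlated (median estimated correlation 0.39), so their counts are not independent.

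All 37 genes of the interferon gamma response rose, and 37 adjusted over the list alone, with a median log2 fold change of 3.26 (adjusted p = 0.0484 with an estimated correlation). Iigp1, a GTPase that acts against intracellular pathogens, rose 58.9-fold, Zbp1 13.6-fold and the immunoproteasome subunit gene Psmb9 6.87-fold. Of the 21 genes of cytotoxic and type 1 lymphocytes 19 rose, and 19 adjusted over the list alone (median 3.10, adjusted p = 0.0212 with an estimated correlation). The granzyme genes Gzmb and Gzma rose 91.7-fold and 91.9-fold and the chemokine gene Ccl5 21.4-fold. All 26 genes of the type I interferon response rose, and 26 adjusted over the list alone (median 2.12, adjusted p = 0.101 with an estimated correlation), among them Ifit2 with a log2 fold change of 4.67 ± 0.36, Ifit1bl1 with 2.85 ± 0.25 and Bst2 with 2.24 ± 0.23. Of 9 MHC class II genes 6 rose, and 6 adjusted over the list alone (adjusted p = 0.281 with an estimated correlation). Control 5 was the lowest control for the interferon gamma score, at -3.40 against -2.38 to -2.24 in the other controls, and for the MHC class II score, at -3.82.

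Markers of several blood cell types rose as well. Of 20 macrophage and monocyte genes 19 rose, and 19 adjusted over the list alone (adjusted p = 0.0212 with an estimated correlation), with the complement genes C1qb, C1qc and C1qa at log2 fold changes of 2.29 ± 0.17, 2.02 ± 0.17 and 1.84 ± 0.16. Of 13 neutrophil genes 11 rose, and 11 adjusted over the list alone (adjusted p = 0.0492 with an estimated correlation), S100a8 among them with 5.34 ± 0.70. Of 22 inflammatory cytokine and chemokine genes 15 rose and 2 fell, or 16 and 3 adjusted over the list alone (adjusted p = 0.101 with an estimated correlation). The members that fell were Il18 and Il23a, at -1.95 and -1.64. Of 20 T cell genes 16 rose, and 20 adjusted over the list alone (adjusted p = 0.328 with an estimated correlation), and Cd8a rose by 2.65 ± 0.31. Of 11 genes of the regulatory T cell list 6 rose, and 7 adjusted over the list alone (adjusted p = 0.249 with an estimated correlation), while its defining gene Foxp3 stood at 0.24 ± 0.39 (adjusted p = 0.670). Of 16 plasma cell genes 10 rose, and 11 adjusted over the list alone (adjusted p = 0.396 with an estimated correlation). Igha, the heavy chain of immunoglobulin A, was at 3386 ± 976 CPM in infected and 2238 ± 354 CPM in control samples (log2 fold change 0.60 ± 0.21, adjusted p = 0.0338), a call that was lost under 10 alternatives with adjusted p up to 0.146. None of 19 B cell genes passed, by either adjustment (median 0.23, camera adjusted p = 0.667). The B cell score was -5.31 in control 5 and 0.10 to 0.66 in the other controls, and the T cell score of control 5, -3.83, was also the lowest of the controls.

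Genes tied to type 2 immunity, the arm of the immune system that expels worms, went both ways. Of 16 genes of the list of type 2 cytokines and alternatively activated macrophages 9 rose and 2 fell, or 10 and 2 adjusted over the list alone (adjusted p = 0.249 with an estimated correlation). The cytokine gene Il13 had 1 count in all controls together and 22 in infected samples, a ratio of 28.8 with a 95% counting interval of 4.65 to 1187 (adjusted p = 0.00716). T_muris 1 held 0.680 CPM of Il13 against 0.126 to 0.173 in the 3 other infected libraries, and without it the adjusted p was 0.0432. The 1 count of controls was in control 5. Arg1 and Chil3 rose by 5.01 ± 1.12 and 5.27 ± 1.01 on the log2 scale, while Retnla, a marker of alternatively activated macrophages, fell from 10.2 ± 2.01 to 0.384 ± 0.389 CPM and Ccl17 fell from 0.504 ± 0.364 to 0.0891 ± 0.0905 CPM. Of 12 mast cell genes 8 rose, or 10 with 1 fall adjusted over the list alone (adjusted p = 0.396 with an estimated correlation), and the mast cell protease gene Mcpt1 rose 10.4-fold to 123.2 ± 48.7 CPM. For 2 goblet cell products linked to worm expulsion no change was shown: Retnlb was at 221 ± 105 CPM against 167 ± 48.9 (adjusted p = 0.519) and Ang4 at 143 ± 198 against 83.6 ± 81.9 (adjusted p = 0.545). T_muris 1 held 439 CPM of Ang4 against 27.5 to 75.3 in the other infected libraries, and without it the log2 fold change was -0.92 rather than 0.78. The mucin gene Muc5ac had 0 counts in controls, 5 in infected, 4 at the lower and 2 at the higher dose, too few to test.

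Epithelial genes changed in both directions. Of 20 epithelial antimicrobial and stress genes 9 rose and 2 fell, or 10 and 3 adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Reg3g (ENSMUSG00000030017), a lectin that kills Gram-positive bacteria, rose 12.2-fold and the nitric oxide synthase gene Nos2 16.7-fold, while Pigr, the receptor that carries immunoglobulin A across the epithelium, fell by 1.38 on the log2 scale. Of 30 cell proliferation genes 29 rose, and 29 adjusted over the list alone (median 0.92, adjusted p = 0.203 with an estimated correlation), with Foxm1 up 2.22-fold, Top2a 2.25-fold and Mcm6 1.93-fold. Of 24 colonocyte genes 17 fell and 4 rose, or 17 and 5 adjusted over the list alone (adjusted p = 0.304 with an estimated correlation). The carbonic anhydrase gene Car4 fell from 322 ± 52.7 to 51.1 ± 30.5 CPM and the chloride-bicarbonate exchanger gene Slc26a3 from 1649 to 461 CPM, while Atp12a, a proton pump subunit, rose by 2.92 on the log2 scale. Of 16 tuft cell genes 9 fell and 2 rose, or 11 and 2 adjusted over the list alone (adjusted p = 0.281 with an estimated correlation). Trpm5, a channel of tuft cell taste signalling, fell by 2.17 ± 0.45 on the log2 scale, and the 2 that rose, Alox5ap and Hpgds, are also expressed in leukocytes. Of 16 enteroendocrine genes 8 fell, and 9 adjusted over the list alone (adjusted p = 0.396 with an estimated correlation), Chga among them, from 63.7 ± 11.1 to 20.4 ± 6.26 CPM.

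Of 31 genes of xenobiotic metabolism 27 fell and 2 rose, and 27 and 2 adjusted over the list alone (median -1.74, adjusted p = 0.0558 with an estimated correlation). Cyp2d22 fell by 2.02 ± 0.18, Cyp2d26 by 2.19 ± 0.24 and Fmo1 by 2.02 ± 0.24 on the log2 scale, while Cyp1b1 and Tiparp rose, by 2.49 and 0.71. Of 24 genes of fatty acid oxidation 18 fell, and 19 adjusted over the list alone (adjusted p = 0.244 with an estimated correlation), among them Acadm, an enzyme of mitochondrial fatty acid breakdown, from 175 to 89.2 CPM. All 13 mitochondrially encoded genes fell, and 13 adjusted over the list alone (median -0.81, adjusted p = 0.0212 with an estimated correlation), and the share of counts from mitochondrial genes was 4.36% ± 0.18 in controls and 2.44% ± 0.22 in infected samples (SD, n = 5 and 4). Of 34 nuclear genes of oxidative phosphorylation 17 fell and 1 rose, or 18 and 1 adjusted over the list alone (median -0.27, adjusted p = 0.524 with an estimated correlation). Of 22 genes of the unfolded protein response, which raises protein-folding capacity, 18 rose and 1 fell, or 19 and 1 adjusted over the list alone (adjusted p = 0.0484 with an estimated correlation), with Creld2 up by 1.69 ± 0.12 and Hspa5 by 1.25 ± 0.14 on the log2 scale.

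Of 20 smooth muscle genes 13 fell, and 16 adjusted over the list alone (median -1.02, adjusted p = 0.521 with an estimated correlation), and 6 of 19 genes of enteric neurons and glia fell by either adjustment (median -0.99, adjusted p = 0.555 with an estimated correlation). The preset call of the list of enteric neurons and glia was lost without control 3 (median -0.62, adjusted p = 0.0559), control 5 (-0.61, adjusted p = 0.0695) or T_muris 1 (-0.73, adjusted p = 0.0742). The smooth muscle score ran from -0.51 to 1.40 among controls, wider than in the infected samples, -0.63 to 0.21. Camera did not call the other 17 lists in infected against control samples. Besides B cells these were, by the members that rose and fell, eosinophils with 3 and 0 of 6, goblet cells with 2 and 4 of 19, stem cells with 1 and 5 of 14, germinal centre B cells with 3 and 0 of 10, type 3 lymphocytes with 0 and 3 of 8, dendritic cells with 3 and 1 of 12, fibroblasts with 7 and 1 of 22 and endothelium with 1 and 3 of 15. The rest were adipocytes with 0 and 3 of 8 (0 and 7 adjusted over the list alone), pancreatic acinar cells with 0 and 1 of 3 (1 and 1), NRF2 targets with 6 and 8 of 28, cholesterol biosynthesis with 8 and 3 of 25, circadian clock with 2 and 5 of 17 (2 and 6), heat shock with 4 and 1 of 11 and red blood cells with 0 and 0 of 5. For type 3 lymphocytes the median log2 fold change was 0.03, the mean -0.08 and the test pointed down, and for acinar cells the median was 0.75 and the mean 0.28 while the test pointed down. Of the immediate early genes 6 of 18 rose (camera adjusted p = 0.12), and their score was 1.94 in T_muris 2 against at most 0.30 in each of the other 18 libraries.

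**Figure D1:**
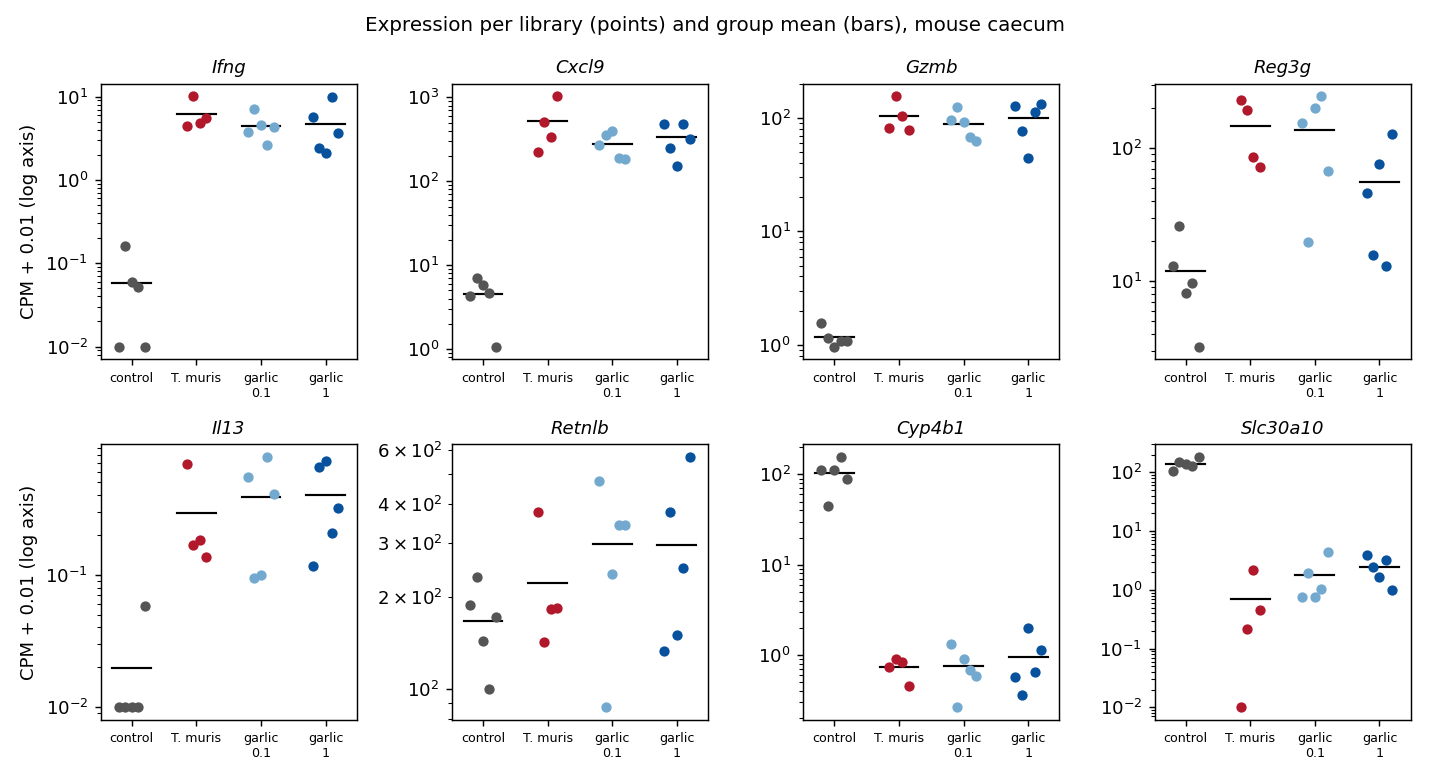
Expression of 8 genes in each of the 19 libraries, in CPM plus 0.01 on a log axis, by group, with 1 point per library and a bar at the group mean. Gzmb averaged 1.15 CPM in controls and 105 CPM in infected samples, and Cyp4b1 103 and 0.720 CPM, with similar levels at both doses, while Retnlb overlapped between all groups.

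The comparison of the lower dose with infected samples asked what 0.1 mg per kg of the extract changed in infected mice. None of the genes that marked infection passed. Ifng was at 4.48 ± 1.63 CPM against 6.23 ± 2.64 in infected samples, Cxcl9 at 281 ± 95.6 against 525 ± 360, Nos2 at 80.6 ± 13.6 against 100.5 ± 65.3, and Reg3g at 138 ± 93.4 against 146 ± 79.0 (SD, n = 5 and 4). Mean levels of Ido1, 230 against 582 CPM, of Mcpt1, 375 against 123.2 CPM, and of Ang4, 309 against 143 CPM, differed more, with single libraries of Ido1 from 118 to 396 against 119 to 1637 CPM. The highest of these was T_muris 4, and without it the log2 fold change of Ido1 was 0.00 rather than -1.34 and that of Cxcl9 -0.34 rather than -0.90, while that of Nos2 turned from -0.32 to 0.23. Mcpt1 ran from 33.4 to 1082 CPM at the lower dose, and without the highest library, replicate 1, its log2 fold change was 0.69 rather than 1.61. That of Ang4 was 2.78 rather than 1.11 without T_muris 1, and that of Ifng -0.14 rather than -0.48 without T_muris 2. That of Reg3g, -0.08, turned positive without T_muris 1 (0.23), T_muris 2 (0.09) or replicate 2 (0.20) or 5 (0.09) of the lower dose. The smallest unadjusted p belonged to Myrf (ENSMUSG00000036098), a membrane-bound transcription factor, at 2.33 ± 0.791 against 0.517 ± 0.187 CPM, and to Pkhd1l1 (ENSMUSG00000038725) at 2.35 ± 1.11 against 0.584 ± 0.253 CPM.

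No gene passed in edgeR. The count at an unadjusted p under 0.05 was 775, with 952.5 expected by chance, and the smallest adjusted p was 0.556. DESeq2 called 3 genes, Myrf (log2 fold change 2.15, adjusted p = 0.00558), Upk3b (3.49, adjusted p = 0.0118) and Pkhd1l1 (1.98, adjusted p = 0.0197), all higher with garlic, and limma voom called 0. For the readouts fixed beforehand the unadjusted 95% intervals of the log2 fold change were -1.37 to 0.42 for Ifng, -1.88 to 0.07 for Cxcl9, -2.59 to -0.09 for Ido1, -1.04 to 0.41 for Nos2, -1.13 to 1.90 for Il13, -0.57 to 1.42 for Retnlb, -0.95 to 3.16 for Ang4, -1.62 to 1.46 for Reg3g, 0.00 to 3.21 for Mcpt1, -0.56 to 1.09 for Foxp3 and -0.34 to 0.58 for Igha. Among the 5 genes with the smallest p that did not pass were also Kcnab3 at -1.68 ± 0.36, 9330160F10Rik at 1.24 ± 0.29 and Gm8242 at -0.94 ± 0.22. The log2 fold change of Il13 was 1.24 without T_muris 1 and -0.04 without lower dose replicate 4, rather than 0.38, and that of Igha was -0.02 without T_muris 4, rather than 0.12.

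Camera with the preset correlation called 16 lists, 3 upward and 13 downward, but none was called with an estimated correlation (smallest adjusted p = 0.862) or by fry (smallest adjusted p = 0.932), and no member of any list passed over all genes. The interferon gamma list had a median log2 fold change of -0.48 (adjusted p = 0.862 with an estimated correlation), with Gbp2 at -0.91 ± 0.39, Gbp2b at -0.98 ± 0.43 and Ido1 at -1.34 ± 0.59. Without T_muris 4 the median was -0.10 and no longer called by the preset test (adjusted p = 0.119), with Gbp2 at -0.27, Gbp2b at -0.48 and Ido1 at 0.00. The type I interferon list had -0.34, with Oas1a at -0.41, Ifit2 at -0.63 and Ifi44 at -0.69. The cholesterol biosynthesis list had 0.18, with Insig1 at 0.60, Mvd at 0.29 and Msmo1 at 0.34. The lists of proliferation and enteroendocrine cells had -0.11 and -0.36, with Melk at -0.31, Ccnb1 at -0.22, Ccna2 at -0.20, Chgb at -0.69, Gcg at -1.01 and Chga at -0.68. Each of these 4 lists had an adjusted p of 0.862 with an estimated correlation. The proliferation median was -0.04 without T_muris 2, and the enteroendocrine median -0.09 without T_muris 3. The immediate early list had -0.62 (adjusted p = 0.862 with an estimated correlation), and 6 members fell adjusted over the list alone, where Fosb stood at -5.77 ± 1.36, Egr1 at -2.18 and Fos at -2.01. The library T_muris 2 alone held 344 CPM of Fosb and 430 CPM of Egr1. Without it the median of the list was -0.03, Fosb stood at 0.44, Egr1 at -0.07 and Fos at -0.39, and 8 lists were called by the preset test.

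The comparison of the higher dose with infected samples asked the same for 1 mg per kg. The 5 genes with the smallest p were higher with garlic. Upk3b among them marks the mesothelium, the cell sheet that covers the outside of the gut. Myrf and Pkhd1l1 were grouped with Upk3b in a set of mesothelial genes noticed in these data, which is described further below. Myrf was at 2.93 ± 1.35 against 0.517 ± 0.187 CPM, Pkhd1l1 at 2.86 ± 1.00 against 0.584 ± 0.253, and Upk3b (ENSMUSG00000042985), a mesothelial membrane gene, at 4.84 ± 2.91 against 0.280 ± 0.0963 CPM (SD, n = 5 and 4). Ifng was at 4.73 ± 3.15 CPM, Cxcl9 at 337 ± 145 CPM and Ido1 at 288 ± 146 CPM, none of which passed, and Reg3g was at 55.5 ± 47.4 against 146 ± 79.0 CPM (adjusted p = 0.764). The log2 fold change of Ido1 was -1.01, but 0.33 without T_muris 4, that of Cxcl9 -0.64, but -0.07 without T_muris 4, and that of Ifng -0.40, but -0.06 without T_muris 2. No direction of these 3 genes is therefore claimed.

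No gene passed in edgeR here either. The count at an unadjusted p under 0.05 was 1248, with 952.5 expected by chance, and Myrf came closest (log2 fold change 2.48 ± 0.39, adjusted p = 0.0943), followed by Pkhd1l1 (2.26 ± 0.41, adjusted p = 0.237), Upk3b (4.07 ± 0.81), Gm8615 (2.21 ± 0.45) and Nr2c2 (0.37 ± 0.08), each of the last 3 with an adjusted p of 0.384. DESeq2 called 8 genes, 7 higher and 1 lower. These were Myrf (adjusted p = 3.88e-05), Upk3b (7.97e-05), Pkhd1l1 (0.000424), Lrrn4 (0.0168), Igfbp6 (0.0262), Nr2c2 (0.0415) and Gm37805 (0.0434), with Gm6877 (0.0167) the lower one, and limma voom called 0. Myrf also passed in edgeR without the library T_muris_garlic_1 5 (adjusted p = 0.0114) and without the count filter (adjusted p = 0.0402). The unadjusted 95% intervals of the readouts were -1.29 to 0.49 for Ifng, -1.61 to 0.34 for Cxcl9, -2.26 to 0.23 for Ido1, -1.49 to -0.04 for Nos2, -1.02 to 1.96 for Il13, -0.58 to 1.42 for Retnlb, -0.74 to 3.40 for Ang4, -2.94 to 0.15 for Reg3g, -0.58 to 2.56 for Mcpt1, -0.10 to 1.55 for Foxp3 and -0.36 to 0.56 for Igha. The log2 fold change of Nos2 was -0.22 rather than -0.76 without T_muris 4. Without T_muris 1 that of Il13 was 1.32 rather than 0.47 and that of Ang4 3.00 rather than 1.33, and without T_muris 4 that of Igha was -0.04 rather than 0.10.

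Camera with the preset correlation called 15 lists, 3 upward and 12 downward, none of them called with an estimated correlation (smallest adjusted p = 0.429) or by fry (smallest adjusted p = 0.456), and no member passed over all genes. The unfolded protein response had a median log2 fold change of -0.17 (adjusted p = 0.429 with an estimated correlation), and 5 members fell adjusted over the list alone. Creld2 stood at -0.47 ± 0.12, Calr at -0.36 ± 0.10 and the chaperone gene Hspa5 at -0.48 ± 0.14. The epithelial antimicrobial list had -0.52 (adjusted p = 0.429 with an estimated correlation), with Saa2 at -1.48, Ly6a at -0.57 and Tgm2 at -0.55. Without T_muris 2, which held 2.03 CPM of Saa2 against 0.261 to 0.753 in the other infected libraries, Saa2 stood at -0.74, and without T_muris 4 the median of the list was -0.25, Ly6a stood at -0.25 and Tgm2 at -0.21. The proliferation list had -0.21, with Melk at -0.39, Tyms at -0.24 and Cenpf at -0.28, and the oxidative phosphorylation list -0.12, with Ndufa4 at -0.25, Uqcrc2 at -0.22 and Ndufa5 at -0.24. The list of NRF2 targets, genes of the antioxidant response, had -0.18, with Prdx1 at -0.25, G6pdx at -0.29 and Akr1b8 at -0.50. These 3 lists each had an adjusted p of 0.844 with an estimated correlation. The immediate early list had -0.63 (adjusted p = 0.844 with an estimated correlation), and 6 members fell adjusted over the list alone, where Fosb stood at -5.72 ± 1.35, Atf3 at -1.74 and Jun at -1.17. Without T_muris 2, the library high in these genes, its median was 0.18, Fosb stood at 0.50, Atf3 at -0.32 and Jun at -0.27, and 9 lists were called by the preset test. The medians of the proliferation, oxidative phosphorylation and NRF2 lists were then -0.11, -0.05 and -0.11.

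**Figure D2:**
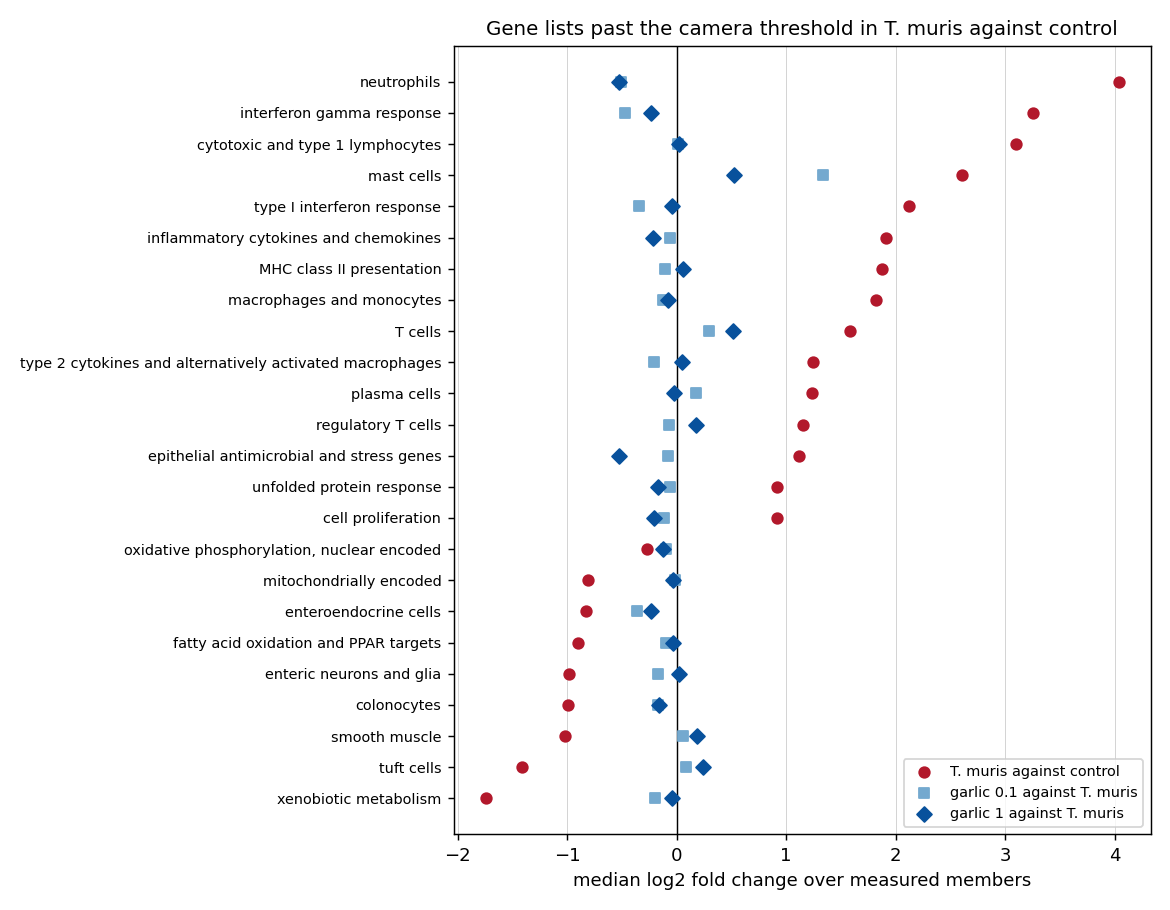
Median log2 fold change over the measured members of the 24 lists called by camera with the preset correlation in infected against control samples (circles), with the same lists for the lower dose (squares) and the higher dose (diamonds) against infected samples. The infection values run from -1.74 for xenobiotic metabolism to 4.04 for neutrophils (3.28 without T_muris 2), and most garlic values lie near 0, with mast cells at the lower dose at 1.34 (adjusted p = 0.862 with an estimated correlation), but at 0.24 without lower dose replicate 1.

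The comparison of the 2 doses asked whether the higher dose differed from the lower. Ak4, an adenylate kinase, was at 40.8 ± 13.8 CPM at the higher and 72.6 ± 18.5 CPM at the lower dose, and Clca4b at 43.7 ± 23.2 against 160 ± 77.97 CPM (SD, n = 5 and 5). No gene passed in edgeR or in DESeq2, limma voom called 0, 321 genes had an unadjusted p under 0.05 with 952.5 expected by chance, and adjusted p was 1.00 for each of the 5 genes with the smallest p, which also included Ak3l2-ps at -1.12, Gm27042 at -0.75 and Gm6877 at -0.69. Camera with the preset correlation called 8 lists, 4 in each direction, but with an estimated correlation (smallest adjusted p = 0.325) and by fry (smallest adjusted p = 0.943) none was called. The type I interferon list had a median of 0.35 (adjusted p = 0.858 with an estimated correlation), with Rsad2 at 0.94, Mx1 at 0.57 and Cmpk2 at 0.39, and the interferon gamma list 0.28 (adjusted p = 0.858 with an estimated correlation), with Nos2 at -0.44, Tgtp1 at 0.53 and Gbp7 at 0.32. The unfolded protein response had -0.13 (adjusted p = 0.325 with an estimated correlation), with Manf at -0.23 and Pdia4 at -0.19, and the epithelial antimicrobial list -0.27 (adjusted p = 0.325 with an estimated correlation), with Saa1 at -0.61, Pla2g2a at -0.94 and Reg3g at -1.32. The lists of xenobiotic metabolism and proliferation had 0.18 and -0.08 (adjusted p = 0.858 with an estimated correlation for both), with Ces2a at 0.92, Ces2c at 0.37, Abcb1a at 0.53, Birc5 at -0.19, Tyms at -0.12 and Foxm1 at -0.16. The proliferation median was 0.01 without lower dose replicate 5. The lists of regulatory T cells and mitochondrially encoded genes had 0.24 and -0.05 (adjusted p = 0.858 with an estimated correlation for both).

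Infected samples at either dose were also compared with controls, to ask how far they stood from uninfected tissue. At the lower dose Ighg2c rose 127-fold, Gzma 96.4-fold and the mast cell protease gene Cma2 by 6.53 ± 1.09 on the log2 scale, a call that was lost with limma voom (adjusted p = 0.0692). The log2 fold changes of Cyp4b1, Cyp4f15 and Slc30a10 were -7.10, -6.96 and -6.33. At the higher dose Ighg2c rose 99.6-fold, Gzmb 86.6-fold and Ifng 86.1-fold, and those of the same 3 genes were -6.80, -5.90 and -5.82. Cma2 stood at 5.85 without lower dose replicate 1 and at 7.12 without control 2, Slc30a10 at -7.02 without lower dose replicate 5, and Cyp4f15 at the higher dose at -7.80 without its replicate 1, while 3 of the 5 counts of Ifng in controls were in control 2. At the lower dose 7604 genes passed in edgeR, 4088 higher and 3516 lower, or 3018 and 4596 with upper-quartile scaling. At the higher dose 7643 passed, 4232 higher and 3411 lower, or 3043 and 4500 with upper-quartile scaling. Without control 5 and T_muris 2 the counts were 6647 and 6518.

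The gene groups that moved against control at both doses were largely those of the infected samples. All 37 interferon gamma response genes rose at each dose, and 37 adjusted over the list alone, with medians of 2.97 and 3.24 (adjusted p = 0.0562 and 0.0563 with an estimated correlation). Iigp1 rose 36.5-fold and 47.4-fold, Zbp1 9.77-fold and 12.0-fold and Psmb9 5.19-fold and 6.16-fold. Of 21 cytotoxic lymphocyte genes 19 and 20 rose, the same counts as adjusted over the list alone (adjusted p = 0.0255 and 0.0261 with an estimated correlation), with Gzmk up by 6.06 and 5.94 on the log2 scale. Of 26 type I interferon genes 24 and 26 rose, or 25 and 26 adjusted over the list alone (adjusted p = 0.174 and 0.132 with an estimated correlation), with Ifit2 up by 4.03 and 4.40, Ifit1bl1 by 2.80 and 2.76 and Parp14 by 1.64 and 1.87. Of 20 macrophage genes 19 rose and 1 fell at each dose, and the same adjusted over the list alone (adjusted p = 0.0440 and 0.0422 with an estimated correlation), with C1qb up by 2.15 and 2.18 and the scavenger receptor gene Cd163 the one that fell. Of 31 xenobiotic metabolism genes 27 fell at each dose, and 28 adjusted over the list alone (adjusted p = 0.0530 and 0.0582 with an estimated correlation), with Cyp2d22 down by 1.92 and 1.79 and Ces2e by 2.18 and 2.08 on the log2 scale.

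At the lower dose 21 of 24 fatty acid oxidation genes fell, and 21 adjusted over the list alone (adjusted p = 0.174 with an estimated correlation), with Acadm at -0.96 and Acot1 at -1.66. At the higher dose all 13 mitochondrially encoded genes fell, and 13 adjusted over the list alone (adjusted p = 0.0125 with an estimated correlation), with mt-Co1 at -1.12, mt-Nd4 at -0.74 and mt-Nd6 at -0.90. The share of counts from mitochondrial genes was 2.35% ± 0.05 and 2.26% ± 0.13 at the lower and higher dose (SD, n = 5 each) against 4.36% ± 0.18 in controls. Camera with the preset correlation called 26 and 27 lists, and 3 at each dose with an estimated correlation, the lists of cytotoxic lymphocytes, macrophages and mitochondrially encoded genes.

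Genes that rose with infection alone and with infection at the lower dose overlapped by 3347, where independent lists would share 844, and those that fell by 2794, against 621. At the higher dose 3257 rose in both, against 874, and 2671 fell in both, against 603. Because these comparisons share the control libraries, the controls were also divided so that none was shared. The mean overlap was then 1953 and 1784 genes at the lower dose, against 385 and 341, and 1885 and 1700 at the higher dose, against 387 and 323. A total of 2 genes passed in opposite directions, Pkhd1l1 and Gm8615, which were lower in infected samples (-1.25 and -1.22) and higher at the higher dose (1.01 and 0.99) than in controls.

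Whether garlic moved genes against the infection change was asked across all 19050 genes, which are not independent replicates. The covariance of the log2 fold changes was -0.0541 for infection and the lower dose (r = -0.199) and -0.0766 for infection and the higher dose (r = -0.268). Simulations of unchanged groups gave -0.0568, from -0.0614 to -0.0531, and -0.0570, from -0.0611 to -0.0525, because the infected libraries stand on opposite sides of both comparisons. With those libraries divided so that none was shared, the mean was 0.0122, from -0.0517 to 0.0865, for the lower dose and -0.0102, from -0.0748 to 0.0647, for the higher dose. For the 2 doses the covariance was 0.0698 (r = 0.713), against 0.0569, from 0.0529 to 0.0621, in simulations of unchanged groups (r = 0.567), and 0.00338, from -0.00577 to 0.0210, with no library shared. The values for the higher dose and for the 2 doses lay outside the simulated ranges. The simulations drew each gene independently, while genes of the same list had a median estimated correlation of 0.39 to 0.41 in these comparisons. The simulated ranges are therefore too narrow, and no conclusion is drawn from values outside them. Without shared libraries none of the 3 covariances was larger than the spread over the 6 divisions.

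**Figure D3:**
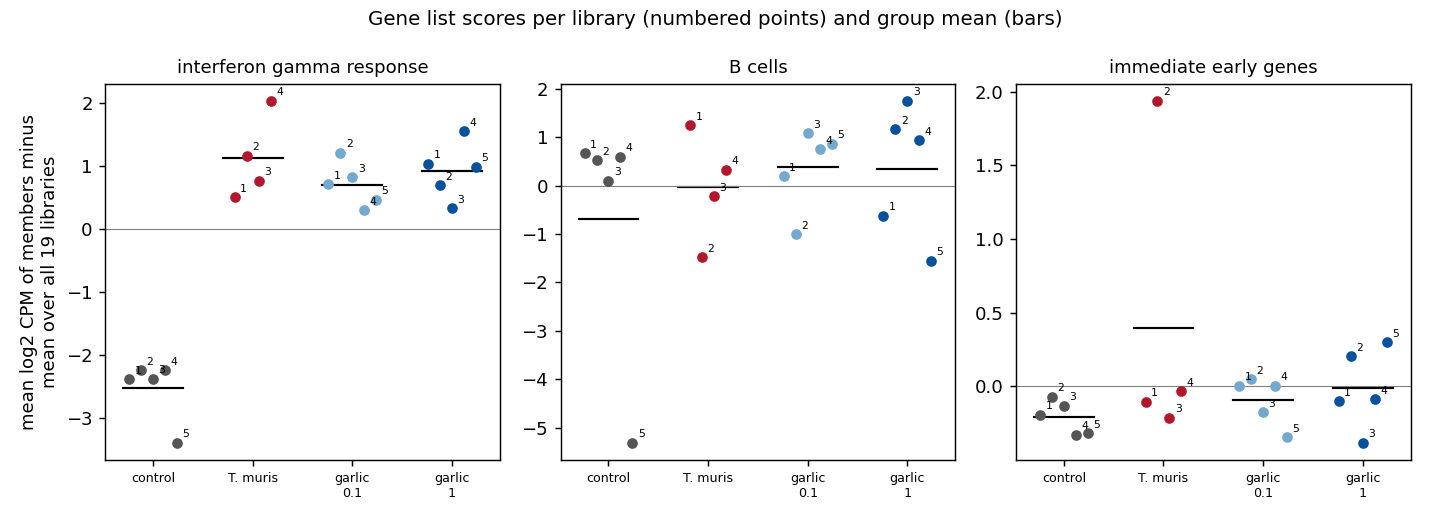
Scores of 3 gene lists in each library, as the mean log2 CPM of the members minus their mean over all 19 libraries, by group, with numbered points for libraries and bars for group means. Control 5 has the lowest B cell score, -5.31, and T_muris 2 the highest immediate early score, 1.94, while the interferon gamma scores of all infected libraries lie above those of all controls.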

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

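The tests on control 5, on immediate early genes and on smooth muscle were chosen after the result was seen, while the splits of the samples and the test of held-out mesothelial genes were written down before their results were seen. A single library stood apart from its group in 39 of 588 groups of samples, 20 of 424 for named genes and 19 of 164 for gene lists. Chance flags about 1 in 20 groups, or 29.4 here. Control 5 held 16 of the 39.

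In control 5 the scores were low for B cells (-5.31), T cells (-3.83), MHC class II (-3.82), the interferon gamma response (-3.40), plasma cells (-3.18), regulatory T cells (-2.20), germinal centre B cells (-2.01), dendritic cells (-1.91), inflammatory cytokines (-1.79), type 3 lymphocytes (-1.71) and tuft cells (0.35). Its CPM was low for Cxcl9 (1.06), Psmb9 (17.4) and Bst2 (14.2), and high for G6pdx (112). Il13 (0.0483) was also flagged as high, but that lies under the 0.138 CPM that 3 counts make in this library, so it may be counting noise. A piece of wall without a lymphoid follicle is a candidate explanation for the low B cell score. In its favour, 9 genes of follicle stroma and lymphocyte homing scored -3.95 in control 5, which is 4.46 under the lowest other control (difference -4.46). Against it, plasma cell genes were expected within the range of the other controls, -1.23 to -0.69, and lay below, so it stays open. A wrong label, an infected sample named control, was argued against, since the interferon gamma score lay below the lowest infected library (difference -3.70, SD of infected libraries 0.485). No biological explanation was tested.

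T_muris 2 held 344 CPM of Fosb and 430 CPM of Egr1 and the highest immediate early score of all libraries, 1.94. The lower immediate early genes with garlic may come from this 1 library, because without it the median log2 fold change at the higher dose was 0.183. Stress during handling of T_muris 2 stays open: its heat shock score, 0.476, lay 0.318 above the highest of the 3 other infected libraries, but control 5 and higher dose replicate 4 each had 0.360 with immediate early scores of -0.32 and -0.09, and the SD of the other 18 libraries was 0.306. A response to infection in this sample stays open, as untested.

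Genes of the mesothelium were among those with the smallest p in the garlic comparisons. Those noticed first were Upk3b, Lrrn4, Bnc1, Nkain4, Myrf, Pkhd1l1, Upk1b and Igfbp6. They include Myrf, Upk3b and Pkhd1l1, which DESeq2 called at both doses, and Lrrn4 and Igfbp6, which it called at the higher dose. A score of 5 held-out mesothelial genes, Wt1, Gpm6a, Rspo1, Aldh1a2 and Muc16, was higher by 0.85 ± 0.18 (SE) in the 10 garlic libraries than in the 4 infected ones (exact two-sided permutation p = 0.00899, 0.0180 adjusted over 4 scores). It lay above the highest infected library in 9 of 10. The 4 scores included that of the genes noticed first, which were picked from these data, so the adjusted p may be too small. A broader set of 18 held-out genes was higher by 0.29 ± 0.07 (exact p = 0.0140). Of the 5 genes Rspo1 (-0.17 and 0.05 at the lower and higher dose) and Aldh1a2 (0.08 and 0.32) moved least, and Wt1 averaged only 0.199 CPM in infected samples. The held-out genes were scored in the same libraries in which the pattern was first seen, and genes of 1 cell type vary together. An exact p for them is therefore not independent evidence of a difference between the groups. The 5-gene score was -0.07 ± 0.49 in controls, -0.58 ± 0.16 in infected and 0.27 ± 0.50 in garlic libraries (SD). Muc16 was at 25.0 CPM in controls, 3.10 in infected samples, and 5.43 and 6.80 at the lower and higher dose. It alone of the 5 genes passed in infected against control samples. The log2 fold changes of the others were -0.56 for Gpm6a, -0.46 for Aldh1a2, 0.83 for Rspo1 and 1.04 for Wt1. More mesothelium in the pieces from garlic groups, or less in the 4 infected pieces, may underlie the pattern. More of all outer wall layers in equal proportion stays open as well: the smooth muscle score differed by 0.142 ± 0.215 (SE), and the mesothelial score minus the smooth muscle score was higher with garlic by 0.71 ± 0.27 (exact p = 0.00799) for the 5 genes but by 0.15 ± 0.21 (exact p = 0.355) for the 18. An effect of garlic or of infection on the mesothelium stays open, as untested.

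The other single libraries that stood apart were as follows. In controls, Ces2e was low in control 2 (517 CPM) and Saa2 in control 4 (0 CPM). In infected samples, Il13 was high in T_muris 1 (0.680 CPM), Saa1 low (116 CPM), Acot1 high (7.13 CPM) and the epithelial antimicrobial score low (0.27) in T_muris 3, and Gzmk (4.77 CPM) and the NRF2 score (-0.35) low in T_muris 4. At the lower dose, Ces2e was high (174 CPM) and the eosinophil score low (-0.52) in replicate 2, Cyp2d26 low in replicate 4 (17.6 CPM) and Pdia4 high in replicate 5 (289.7 CPM). At the higher dose, the type 2 score was low in replicate 1 (-0.10), Pdia4 low in replicate 2 (179.8 CPM), and Saa2 (0.71 CPM) and the scores of endothelium (0.25) and circadian clock (0.28) high in replicate 3. Chgb (73.6 CPM), Gcg (20.8 CPM) and the enteroendocrine score (0.59) were high in replicate 5. Among loci without a gene name, which the comparisons of the report do not use, 185 of 567 passed in infected against control samples, 63 higher and 122 lower.

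For each comparison 100 of 126 splits of its samples were tested, the real one included. For genes, no other split gave as many calls for infected against control (7298, highest other 5040, 1 of 100 splits), for the lower dose against control (7604, highest other 1, 1 of 100) and for the higher dose against control (7643, highest other 3224, 1 of 100). A chance division of the samples is therefore unlikely in these comparisons, though 1 of 100 is the smallest share that this test can give. The splits cannot address a difference in processing between the groups. For the lower dose against infected samples (0, highest other 1, 100 of 100), the higher dose against infected samples (0, highest other 3342, 100 of 100) and the 2 doses (0, highest other 524, 100 of 100) the real count was 0, which every split reaches, so the splits say nothing about chance there. These counts of 0 are from edgeR, with 775, 1248 and 321 genes at an unadjusted p under 0.05, while DESeq2 called 3, 8 and 0 and limma voom 0, 0 and 0. The splits with 3342 and 524 genes point to a structure of the samples other than dose. Each had the largest B cell difference of its 100 splits, -1.98 and 1.61, and no other source of this structure was tested. The split with 5040 genes was the real one but for control 2, and that with 3224 genes the real one but for control 2 and higher dose replicate 5, so both largely kept infected and control libraries apart. For lists called by camera with the preset correlation the splits cannot exclude chance in any comparison. In the comparisons with control, no other split has equal shares of infected libraries on both sides. Part of the infection difference can therefore remain in those splits, and their list counts do not show what chance alone gives. As many lists came in 34 of 100 splits for infected against control (24, highest other 31), in 32 for the lower dose against infected samples (16, highest other 20) and in 65 for the higher dose against infected samples (15, highest other 24). For the 2 doses it was 99 (8, highest other 22), for the lower dose against control 16 (26, highest other 30) and for the higher dose against control 23 (27, highest other 30).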

How the results depend on the processing

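The alternatives chosen after the data were seen were loci without a gene name kept, the B cell score as a covariate, and control 5 and T_muris 2 both left out. Over all alternatives, 304 counts of genes and lists stayed within 1.5 times and 26 moved further. Of 5356 values of named genes 5336 kept their side of the threshold, 11 were lost and 9 gained. Of those past the threshold in at least 1 fit, 0 reversed. Of 2849 values past it in neither fit, 17 changed sign. Of list values 2396 kept the direction of the test and their side of the threshold, 266 were lost and 6 reversed. A minimum absolute log2 fold change of 1 left 2759, 2842 and 2794 genes for infected, lower dose and higher dose against control, by its construction. DESeq2 called 3 and 8 genes at the lower and higher dose against infected samples, and without the count filter 1 passed at the higher dose (the cause was not tested). With an estimated correlation 6 lists were called for infected against control, 0, 0 and 0 in the garlic comparisons, and 3 and 3 for the doses against control, and fry called 0, 0 and 0 in the garlic comparisons (the cause was not tested). With control 5 and T_muris 2 left out 10 lists were called for the lower dose against infected samples, and the immediate early median at the higher dose was 0.183, with fewer samples. Without each library in turn, genes for infected against control ran from 6047 (without T_muris 4) to 7544, for the lower dose against control from 6539 to 7840, for the higher dose against control from 6431 to 8079, and for the higher dose against infected samples from 0 to 1 (without its replicate 5). Lists ran from 8 (without T_muris 2) to 22 (without lower dose replicate 2), from 9 (without T_muris 2) to 16, and from 5 (without lower dose replicate 5) to 17 (without higher dose replicate 3) for the lower dose, the higher dose and the 2 doses. Medians reversed for xenobiotic metabolism at the lower dose (-0.32 to 0.0495, without T_muris 3), the interferon gamma response at the higher dose (-0.40 to 0.142, without T_muris 4), immediate early genes at the higher dose (-0.85 to 0.183, without T_muris 2) and proliferation between doses (-0.14 to 0.0135, without lower dose replicate 5), and the test turned for mast cells at the lower dose (0.240 to 1.63, lowest without lower dose replicate 1); the cause was not tested. With no infected library shared, the covariances of infection and each dose and of the 2 doses were 0.0122, -0.0102 and 0.00338, and with a mean CPM of at least 5 they were -0.0222, -0.0330 and 0.0316. With the replicate number as a block 1 gene passed at the higher dose against infected samples, Myrf (log2 fold change 2.53, adjusted p = 0.0133). The numbers do not pair the samples, since over 27 pairs of the same number the median correlation was 0.0020 and 6 of 19 libraries were closest to one of their own number. Depth limits genes with few counts, such as Il13 with 22 counts in infected samples.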

Other observations

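These gene families were chosen after the data were seen, and reads shared between close paralogs were not separated. Directions are for infected against control samples (n = 4 and 5) and held with TMM, RLE and upper-quartile scaling unless a difference is given. Of all genes 20.6% rose and 17.7% fell, or 15.7% and 23.6% with upper-quartile scaling.

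Among immunoglobulin G heavy chains 3 of 4 rose. Ighg2b rose by 3.09 ± 0.81 (SE, adjusted p = 0.00642) and Ighg1 by 3.01 ± 0.77 (adjusted p = 0.00553) on the log2 scale beside Ighg2c, and Ighg3 stood at 0.84 ± 0.81 (adjusted p = 0.444). Of 10 Ly49 receptors, carried by natural killer cells, 9 rose, Klra3 by 3.35 and Klra7 by 2.33. Of 16 nonclassical MHC class I genes 11 rose, with H2-Q7 at 2.32 and H2-Q4 at 2.12. Of 6 schlafen genes 4 rose, and Slfn4 rose from 18.8 to 372 CPM.

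All 9 measured UDP-glycosyltransferase genes with Ugt symbols fell, Ugt8a among them. Of 13 carboxylesterases 10 fell and 1 rose, Ces2f by 3.35 ± 0.66. Of 41 cytochrome P450 genes 23 fell and 4 rose, or 24 and 1 with upper-quartile scaling. Of 293 solute carriers 98 fell and 45 rose, or 117 and 34 with upper-quartile scaling. Of 32 chemokines 19 rose and 3 fell, or 18 and 5 with upper-quartile scaling, and Ccl28, a chemokine of the mucosa, fell from 105.4 to 37.2 CPM. Of 12 Toll-like receptors 9 rose and 1 fell, or 7 and 1 with upper-quartile scaling, and the receptor for flagellin, Tlr5, fell by 1.54 ± 0.30. Of 16 TRP channels 7 fell and 3 rose, and the magnesium channel gene Trpm6 fell from 200.3 to 17.65 CPM.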
